A study of Mus musculus with 8 samples.

How the data were processed

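The data are 8 reduced representation bisulfite sequencing libraries from dissected mouse brain tissue, labelled the dDG DGC layer, of 4 mice that self-administered cocaine and 4 saline mice. Groups and replicate numbers were taken from the sample titles, and the series' design text gives 4 mice per group. Reads were converted with bcl2fastq and processed with Bismark version 22.1 against mm10, per the submitters' processing notes. Trimming and any removal of duplicate reads are not given in the sources used here. Each file lists 1 cytosine of a CpG per line and strand, with its methylation level and coverage. Per the file headers the level is named as a percent, and the deposited values are a fraction from 0 to 1, which was multiplied by 100. The deposited coverage is a count of reads with a minimum of 10 per cytosine in each file. Level times coverage gave a whole number of methylated reads at 100% of cytosines, within a distance of 5e-07 times the coverage, so methylated and unmethylated read counts were recovered by rounding.

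Reduced representation libraries carry no molecular identifiers in the labels used here, so reads from 1 fragment end may be copies of few molecules, and counting errors alone understate the error. Spread between mice therefore entered each main test, at single cytosines only through a trend shared across cytosines. Reads were joined by chromosome, base and strand. The mitochondrial chromosome and unplaced contigs were left out of the comparisons, and chromosomes X and Y were kept. Cytosines with at least 10 reads in all 8 samples entered the comparisons, with strands kept apart. Tested cytosines, regions and gene ends had a pooled level from 5% to 95%. Regions were runs of common cytosines with gaps of at most 100 bp and at least 3 CpGs, 125876 in all, of which 92484 passed the filter on level. The tested regions had a median length of 106 bp, a median of 4 CpGs and a median of 48.7 reads per cytosine and sample. Regions were made without the group labels.

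Gene positions came from a RefSeq gene table of assembly GRCm38.p6, whose primary chromosomes have the coordinates of mm10. The table gives no strand and no exons, so promoters, exons and introns could not be placed, and CpG islands were not analysed here. Windows of 1 kb either side of both ends of each protein-coding or long noncoding RNA gene, with at least 5 cytosines, took the place of promoters. A region was assigned to a gene end within 1 kb first, then to a gene that holds it, then to the nearest protein-coding gene within 50 kb. Coordinates are counted from 1.

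Sites, regions and gene ends were tested by quasi-binomial logistic regression of methylated and unmethylated reads on group. The Pearson dispersion was moderated across features with limma's squeezeVar, with a trend on log coverage and a floor of 1, followed by an F test and Benjamini-Hochberg adjustment. At single cytosines the prior degrees of freedom were infinite, so each dispersion was replaced by the trend. A cytosine's own spread between mice thus did not enter its p. For regions and gene ends the prior degrees of freedom were 11.4 and 9.67. A site or region was called at an adjusted p under 0.05 and a difference in mean level of at least 10 points, and a gene end at a difference of at least 5 points. Mean levels of sets of cytosines and of gene lists were compared by a two-sided exact permutation test over the 70 assignments of 8 samples, adjusted within each family of 7 sets or 40 list tests. The 20 gene lists hold 755 entries, of which 754 matched the gene table. Each list value is the mean over member genes, weighted equally, minus the mean over all protein-coding genes. The number of members with a region at an unadjusted p under 0.05 was compared with 10000 random lists matched on the number of tested regions, since no region was called. In the protocadherin clusters many genes share the same regions, so that count is not independent evidence there.

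The tests, lists, rule for named genes and most alternatives were set before the data were examined. The rule took the regions past the threshold first, then the smallest p values up to 8 per direction and 1 per gene, 5 per direction for gene ends, up to 3 members per list by the smallest region p, and the 5 best covered imprinted gene ends. Replicate libraries were compared pairwise for possible copies. The lowest chi-square per region among the 28 pairs was 4.74, so no library repeats the reads of another, and all 8 were kept as separate samples. The value of 1 for equal levels holds only for independent reads. Where reads are copies of few molecules, libraries from the same mouse would exceed it too, so this check cannot exclude them.

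The tests were checked on simulated reads drawn from a beta-binomial distribution for the real features and depths, with 200 changed features, 50 of each size. Changed features were drawn from intermediate pooled levels only, and all 200 were changed together. The shares called therefore do not cover low or high levels or isolated changes. Of regions changed by 10, 20, 30 and 40 points, 2%, 42%, 88% and 96% were called among 89237, with 12 false calls in 126. Of gene ends, 20%, 84%, 100% and 100% were called among 7179, with 11 false calls in 163. Of single cytosines, 0%, 0%, 6% and 22% were called among 613307, with 1 false call in 15. Among unchanged simulated features, 5.89% of regions, 5.86% of gene ends and 6.22% of cytosines had an unadjusted p under 0.05. Simulated features of similar depth shared 1 spread between samples, so these shares need not hold for the real reads. Adding 3 points to the interiors of 1 list gave a centred difference of 2.99 points at an exact permutation p of 0.0286, the smallest possible.

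Alternatives were coverage minimums of 20 and 30, cytosines covered in at least 3 samples per group, merged strands, no filter on level, other gaps, CpG numbers and windows, tests without overdispersion, Fisher's exact test on pooled reads, limma on logit values with 0.5 reads added, other minimum differences, removal of chromosomes X and Y, the replicate number as a block, and leaving out each sample. Calls were also counted over the 35 splits of the 8 samples into 4 and 4. Work was done in R 4.3.3 with limma 3.58.1, and in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.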

Results

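CpG methylation was measured by reduced representation bisulfite sequencing, in which CpG-rich restriction fragments are read after bisulfite treatment. The tissue is labelled as the dDG DGC layer of male C57 BL/6 mouse brain, read here as the granule cell layer of the dorsal dentate gyrus. DNA came from 4 mice after cocaine self-administration and from 4 saline mice, with 1 library per mouse. Each library listed between 1844706 and 2236384 cytosines, each with at least 10 reads. The reads summed over cytosines came to 88426664, 116317068, 87964952 and 97900818 in cocaine 1, 2, 3 and 4, and to 125475727, 102632052, 141775386 and 114119783 in saline 1, 2, 3 and 4. Median coverage per cytosine lay between 34 reads in cocaine 3 and 66 reads in saline 3. All 8 libraries covered 1510385 cytosines, which is 48.7% of the 3101292 listed in any library, and the comparisons rest on these. Saline 1 stood apart from the other libraries. At cytosines of intermediate level with 30 to 40 reads, 18.7% of its values were exactly 0% or 100%, against 0.883% to 4.26% in the other 7 libraries.

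The series title sets the work in hippocampal learning about cocaine reward, so the first question was whether cocaine self-administration went with another overall methylation level in this layer. Mean methylation over the common cytosines was 37.3% ± 0.697 (SD, n = 4) in cocaine mice and 38.0% ± 0.168 (SD, n = 4) in saline mice. Sequence between genes had the highest mean, at 68.3% ± 0.859 in cocaine and 69.2% ± 0.310 in saline mice. Cytosines inside genes averaged 51.0% ± 1.01 and 52.0% ± 0.358, and those within 1 kb of a gene's end averaged 8.46% ± 0.331 and 8.79% ± 0.0968. Cytosines of intermediate level, from 20% to 80%, averaged 53.0% ± 2.11 in cocaine and 55.3% ± 1.43 in saline mice.

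The cocaine mean was below the saline mean in each of these classes, yet no difference passed the test. Over all common cytosines the difference was -0.733 percentage points (two-sided exact permutation p = 0.114, adjusted p = 0.160). At intermediate cytosines it was -2.25 points (exact p = 0.171, adjusted p = 0.171), and between genes it was -0.945 points (exact p = 0.0857, adjusted p = 0.160). Cocaine 4 overlapped the saline mice at 38.2%, and cocaine 3 was the lowest of the 8 at 36.5%. Without cocaine 3 the overall difference was -0.460 points (exact p = 0.229). The smallest p that 4 against 4 mice can give is 0.0286.

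**Figure D1:**
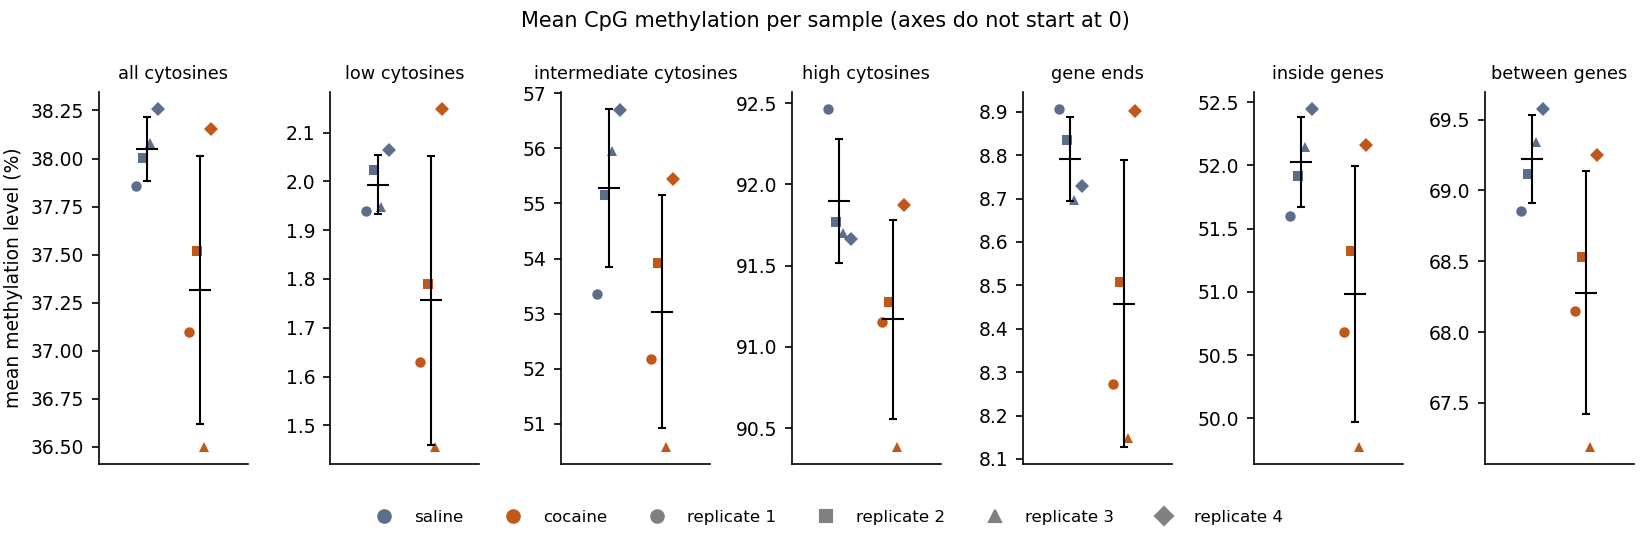
Mean CpG methylation of each sample in percent (vertical axes, each with its own range and not starting at 0) over all common cytosines, over cytosines of low, intermediate and high level, and over gene ends, gene interiors and sequence between genes. Symbols are samples, horizontal marks are group means and bars are SD (n = 4). Over all common cytosines the cocaine mean is 37.3% and the saline mean 38.0%, with cocaine 4 at 38.2% among the saline samples.

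At single cytosines, 1 of the 666028 tested passed an adjusted p under 0.05 with a difference of at least 10 points. It lies on the minus strand of chromosome 7 at base 45078491 (mm10), within 1 kb of an end of Nosip, which encodes a nitric oxide synthase interacting protein. Its methylation rose from 46.5% ± 17.0 in saline to 86.9% ± 12.3 in cocaine mice (n = 4 each, adjusted p = 0.000367), on 36 to 130 reads per sample. That adjusted p rests on the trend of dispersion and does not measure the spread at this cytosine. Its own dispersion was 10.99, against a median of 3.66 over tested cytosines. The neighbouring cytosine on the same strand, at base 45078516, read 81.7% to 91.5% in cocaine and 73.0% to 96.4% in saline mice. The Nosip call was lost when each cytosine kept its own dispersion (adjusted p = 0.945), with limma on logit values (adjusted p = 0.958), and with no filter on level (adjusted p = 0.660). It was also lost with the replicate number as a block (adjusted p = 0.834) and without cocaine 4 (adjusted p = 0.330). The difference was 40.3 points with all samples and 35.9 points without cocaine 4. Merged strands gave 20 calls, 16 of them lower in cocaine mice, and leaving out saline 3 gave 25, of which 22 were lower. Over all 666028 tested cytosines, 56.9% had the lower mean in cocaine mice. At an unadjusted p under 0.05 stood 40647 cytosines, 27427 of them with the lower mean in cocaine mice. Of unchanged cytosines in simulated reads 6.22% reached that unadjusted p, but simulated cytosines of similar depth shared 1 spread between samples. Over the other splits of the real samples into 4 and 4 the median count was lower, at 38822.5. The count of 40647 was reached in 12 of the 35 splits, the real one included.

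Regions of neighbouring CpGs were compared to ask whether cocaine self-administration went with differences spread over several CpGs of a gene. Among regions with a lower mean in cocaine mice, Zfp993, Ctnna3, Zbtb20, Synpo, Cacna1h, Cog6, Ppard and the long noncoding RNA Gm39742 had the smallest p values. Among regions with a higher mean, these were Gm32719, Fbf1, Btg1, Pde6g, Gm43305, Fryl, Rerg and Tcf7l1. None of these 16 regions passed, and none of the 92484 tested did. The quasi-binomial test gave a smallest adjusted p of 0.249, with 5229 regions at an unadjusted p under 0.05 where 4624.2 would pass by chance, and limma on logit values called 0. Of unchanged regions in simulated reads, 5.89% reached that unadjusted p, a rate that the count of 5229 does not exceed. Simulated regions of similar depth shared the same spread between samples, so this rate need not hold for the real reads. Over the other splits of the real samples into equal groups the median count was lower, at 4365.5. The count of 5229 was reached in 7 of the 35 splits, the real one included.

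Within Zfp993, a zinc finger gene, the region at chromosome 4, 146942230 to 146942551, held 39 CpGs and read 30.7% ± 1.59 in cocaine and 45.3% ± 2.54 in saline mice (adjusted p = 0.249). In Ctnna3, which encodes an alpha catenin of cell junctions, the region at chromosome 10, 63785016 to 63785114, read 32.1% ± 9.52 and 61.7% ± 8.41 (adjusted p = 0.249). Within Zbtb20, a transcription factor of hippocampal development, chromosome 16, 43142870 to 43143081, read 81.6% ± 5.66 in cocaine and 94.3% ± 1.35 in saline mice. Synpo encodes synaptopodin, an actin-associated protein of dendritic spines, and its region at chromosome 18, 60652110 to 60652287, read 13.2% ± 1.98 and 28.9% ± 2.82. In Cacna1h, a T-type calcium channel gene, chromosome 17, 25431395 to 25431568, read 20.9% ± 6.05 in cocaine and 44.4% ± 3.32 in saline mice. Ppard encodes a nuclear receptor of lipid metabolism, and its region at chromosome 17, 28277080 to 28277156, read 56.6% ± 6.25 and 86.4% ± 5.06. In Cog6, a gene of the Golgi tethering complex, chromosome 3, 52994651 to 52994663, read 84.7% ± 4.07 and 97.1% ± 2.22. Near an end of Gm39742, chromosome 1, 191929355 to 191929458, read 63.3% ± 5.41 and 82.8% ± 1.79. Each of the last 6 had an adjusted p of 0.573.

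Of the regions with the higher mean in cocaine mice, the one with the smallest p lay outside genes on chromosome 12, 20234199 to 20234380, with Gm32719 as the nearest gene, and read 74.4% ± 2.64 in cocaine and 63.6% ± 1.37 in saline mice (adjusted p = 0.573). In Fbf1, a centriole component gene, chromosome 11, 116146778 to 116146843, read 22.7% ± 1.60 and 6.91% ± 4.09 (adjusted p = 0.663). The other 6 had an adjusted p of 0.876. Near an end of Pde6g, a phosphodiesterase subunit of rod photoreceptors, chromosome 11, 120448126 to 120448214, read 84.1% ± 4.55 and 60.4% ± 8.34. Rerg, a Ras-like growth inhibitor gene, read 58.5% ± 9.04 and 36.9% ± 6.25 at chromosome 6, 137129657 to 137129754. Tcf7l1, a transcription factor of Wnt signalling, read 55.6% ± 7.93 and 34.5% ± 7.01 at chromosome 6, 72730582 to 72730789. Fryl read 97.5% ± 0.861 and 91.1% ± 0.948 at chromosome 5, 73089292 to 73089391. The region near an end of Gm43305, chromosome 14, 54297285 to 54297355, ranged from 46.2% to 85.6% in cocaine and from 0% to 55.8% in saline mice. Near an end of Btg1, an antiproliferative gene, chromosome 10, 96616947 to 96617045, read 14.6% in cocaine 2 and 19.8% in cocaine 4, and 0% in the other 6 samples.

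**Figure D2:**
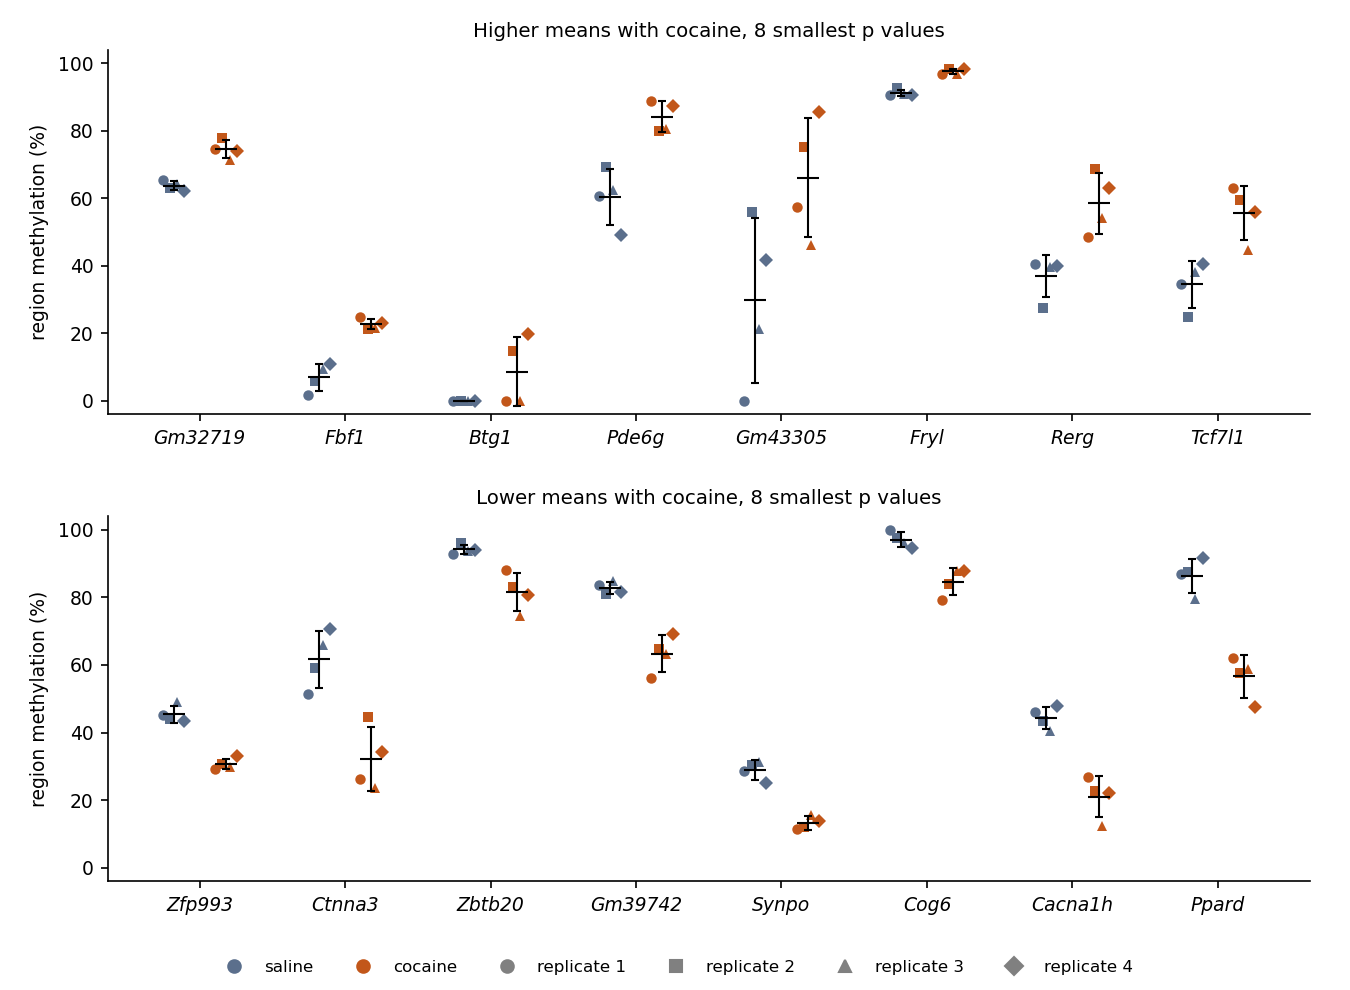
Methylation in percent (vertical axis) of the regions with the smallest p values, 8 with the higher mean in cocaine mice (upper panel) and 8 with the lower mean (lower panel), labelled by gene. Symbols are samples, horizontal marks are group means and bars are SD (n = 4). Zfp993 reads 30.7% in cocaine and 45.3% in saline mice, and no region shown passed the adjusted threshold.

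Of the 5229 regions at an unadjusted p under 0.05, 4229 had the lower mean in cocaine mice, which is 80.9%. Over all 92484 tested regions the share was smaller, at 61.8%, with a median difference of -1.06 points. At regions of intermediate level, 2076 of the 2470 with small p had the lower mean, and the mean difference over all 36232 such regions was -1.95 points. Inside genes 2343 of 2884 such regions were lower, and within 1 kb of gene ends 582 of 689 were. In 3045 of the 92484 regions, 3.29%, the cocaine and saline mice did not overlap, where chance gives 2.86%. Without cocaine 3 the lower share was 69.1%, and without saline 1 and cocaine 3 it was 71.6%.

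Windows of 1 kb either side of gene ends were tested in place of promoters, since the gene table used carries no strand. Unc45a, Hpdl, Cmtm1, Snrnp70 and Gm39742 had the smallest p values of the ends with a lower mean in cocaine mice, and Thegl, Gm43305, Tspan10, Pde6g and Gm40324 of those with a higher mean. The end of Unc45a, a myosin chaperone gene, at chromosome 7, 80324292 to 80326292, read 34.4% ± 7.05 in cocaine and 58.2% ± 8.64 in saline mice (adjusted p = 0.234). Hpdl read 9.02% ± 3.48 and 26.8% ± 8.06 at chromosome 4, 116818907 to 116820907, and Cmtm1 read 12.2% ± 3.59 and 25.2% ± 3.43 at chromosome 8, 104309145 to 104311145 (both adjusted p = 0.234). Snrnp70, a gene of the U1 splicing particle, read 80.2% ± 6.43 and 90.8% ± 1.72 at chromosome 7, 45375454 to 45377454 (adjusted p = 0.714). Thegl read 10.9% ± 7.12 in cocaine and 1.504% ± 0.493 in saline mice at chromosome 5, 77015023 to 77017023 (adjusted p = 0.714). Tspan10 and Pde6g share the same cytosines, at 79.6% ± 3.90 and 62.9% ± 5.74. Their 5 cytosines include the 4 of the Pde6g region above. The ends of Gm39742 and Gm43305 hold the same cytosines as their regions above. The return of these genes here is therefore not independent of the region results. Gm40324 read 90.4% ± 0.770 and 83.4% ± 2.10. None of the 7336 gene ends passed. The smallest adjusted p of the quasi-binomial test was 0.234, limma on logit values called 0, and 424 ends had an unadjusted p under 0.05, 375 of them with the lower mean in cocaine mice. Over all 7336 ends, 64.2% had the lower mean in cocaine mice.

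Extracellular matrix genes, named in the series title, were examined as 3 lists fixed before the data were examined, with integrins and adhesion receptors as another. At the ends of 45 collagen, laminin and basement membrane genes, methylation was 9.80% ± 0.215 in cocaine and 10.1% ± 0.274 in saline mice. Over 55 interiors it was 68.3% ± 0.980 and 69.2% ± 0.385. Centred on all genes, these differences were 0.1004 points (exact permutation p = 0.714) and 0.0621 points (exact p = 0.714). Perineuronal net and proteoglycan genes differed, also centred, by -0.0863 points at the ends of 31 genes (exact p = 0.714). Their centred difference in 36 interiors was -0.226 points (exact p = 0.343). Matrix proteases, inhibitors and crosslinkers differed by 0.194 points at the ends of 40 genes (exact p = 0.371, -0.165 points not centred). Their centred difference in 43 interiors was -0.225 points (exact p = 0.486). Integrins and adhesion receptors differed by -0.372 points at the ends of 35 genes (exact p = 0.400). Their centred difference in 42 interiors was -0.107 points (exact p = 0.657). None of these 4 groups passed.

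Within the matrix lists, 1 region passed when adjusted over the list alone, and 0 passed over all regions. It lies in Adamtsl2, which encodes a secreted glycoprotein of fibrillin microfibrils, at chromosome 2, 27088412 to 27088513, and read 15.1% ± 1.88 in cocaine and 26.7% ± 1.86 in saline mice (adjusted p = 0.0359 over the list alone and 0.663 over all regions). In Mmp24, a membrane-type matrix metalloproteinase gene, a region read 86.2% ± 2.51 and 92.8% ± 2.03, and in Adamts17 one read 90.6% ± 1.48 and 97.1% ± 2.00. Col27a1, a fibrillar collagen gene, read 81.9% ± 5.64 and 92.4% ± 2.39. Hspg2, which encodes perlecan, read 75.3% ± 6.69 and 87.8% ± 2.40, and Tnxb, a tenascin gene, read 28.4% ± 8.30 and 41.7% ± 1.52. Cspg4, which encodes the NG2 proteoglycan, read 46.0% ± 4.502 and 61.1% ± 4.39, Hapln3 read 82.8% ± 6.68 and 94.2% ± 3.88, and Bgn, which encodes biglycan, read 3.13% ± 2.37 and 10.9% ± 7.96. Of the adhesion genes, Cntnap2 read 86.7% ± 3.32 and 95.9% ± 1.62, Nrxn2 6.42% ± 1.89 and 14.01% ± 2.90, and Cdh22 83.6% ± 2.79 and 90.4% ± 2.38. These genes other than Adamtsl2 had an adjusted p of 0.876 over all regions. All 12 were lower in cocaine mice, as were 80.9% of all regions at an unadjusted p under 0.05. Of such regions in the lists, 14 of 21 were lower for collagens and laminins, 14 of 18 for proteases, 12 of 13 for proteoglycans and 21 of 24 for adhesion receptors. Of 54 collagen, laminin and basement membrane genes with a tested region, 12 held one at an unadjusted p under 0.05, against a mean of 21.6 in random lists matched on region number (one-sided permutation p = 0.9995 for a higher count). Nearly all random lists thus held at least as many, and a test for a lower count was not run. For proteases the count was 15 of 44 against 11.05 (p = 0.0948 in the same permutation), and for proteoglycans 9 of 36 against 8.87 (p = 0.555 in the same permutation).

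Synaptic, activity-regulated and reward-related genes were compared next, with list differences again centred on all genes. Glutamate and GABA receptor and synapse organiser genes differed by -0.381 points at the ends of 40 genes (exact permutation p = 0.286). Their difference in 47 interiors was -0.137 points (exact p = 0.543). Within this list the Cacna1h region passed when adjusted over the list alone (adjusted p = 0.0314) and not over all regions (adjusted p = 0.573). Shank3, a postsynaptic scaffold gene, read 3.37% ± 2.90 in cocaine and 9.54% ± 2.43 in saline mice in its region of smallest p, and Dlg2, another scaffold gene, read 9.41% ± 1.93 and 16.6% ± 4.78. Dopamine, opioid and addiction-related genes differed by 0.441 points at the ends of 29 genes (exact p = 0.114). Their difference in 30 interiors was -0.761 points (exact p = 0.200). Cdk5r1, which encodes the p35 activator of Cdk5, read 3.14% ± 1.03 and 8.91% ± 2.46 (adjusted p = 0.0814 over the list alone). The orexin receptor gene Hcrtr1 read 32.2% ± 7.86 and 52.5% ± 11.1, and the delta opioid receptor gene Oprd1 read 21.7% ± 7.15 and 40.1% ± 17.1. Activity-regulated genes differed by 0.238 points at the ends of 37 genes (exact p = 0.200) and by 0.0484 points in 27 interiors (exact p = 0.914). Not centred, these differences were negative, at -0.121 and -0.946 points. Their examples went both ways, with Fos at 17.6% ± 6.18 and 31.8% ± 13.3, Nptx2 at 86.8% ± 3.45 and 77.7% ± 4.60, and Dusp6 at 11.7% ± 2.04 and 7.21% ± 2.13 in cocaine and saline mice. Shank3, Dlg2, Cdk5r1, Hcrtr1, Oprd1, Fos, Nptx2 and Dusp6 all had an adjusted p of 0.876 over all regions.

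Identity genes of dentate granule cells had low methylation at the ends of 18 genes, 2.48% ± 0.168 in cocaine and 2.83% ± 0.390 in saline mice, a centred difference of 0.0110 points (exact permutation p = 1). Their 20 interiors differed by -0.325 points (exact p = 0.429). Within this list Bcl11b, a zinc finger transcription factor gene, read 9.29% ± 5.48 and 25.5% ± 7.67, Dsp, which encodes desmoplakin, 91.3% ± 7.33 and 97.2% ± 2.72, and Prox1, the homeobox gene of granule cell fate, 6.90% ± 4.06 and 11.9% ± 3.54, none past the threshold (adjusted p = 0.876 each). Marker genes of the other hippocampal cell types were compared because dissected tissue can hold them. In 14 tests over 7 such lists, the smallest exact permutation p was 0.114, for the ends of 14 endothelial and mural cell genes at -1.61 points. Oligodendrocyte lineage genes differed by 1.12 points at the ends of 12 genes (exact p = 0.343) and by -1.37 points in 13 interiors (exact p = 0.200). Astrocyte genes differed by -0.796 points in 17 interiors (exact p = 0.143), and microglia and macrophage genes by -1.14 points in 11 (exact p = 0.143). After centring, other lists went the opposite way, with progenitor and immature neuron genes at 0.865 points in 16 interiors (exact p = 0.257) and CA1, CA3 and mossy cell genes at 0.236 points in 20 (exact p = 0.629). Endothelial and mural cell genes differed by 0.233 points in 16 interiors (exact p = 0.714), and astrocyte genes by 0.0622 points at the ends of 16 genes (exact p = 0.971). Without centring these 4 differences were all negative, at -0.130, -0.758, -0.761 and -0.297 points.

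**Figure D3:**
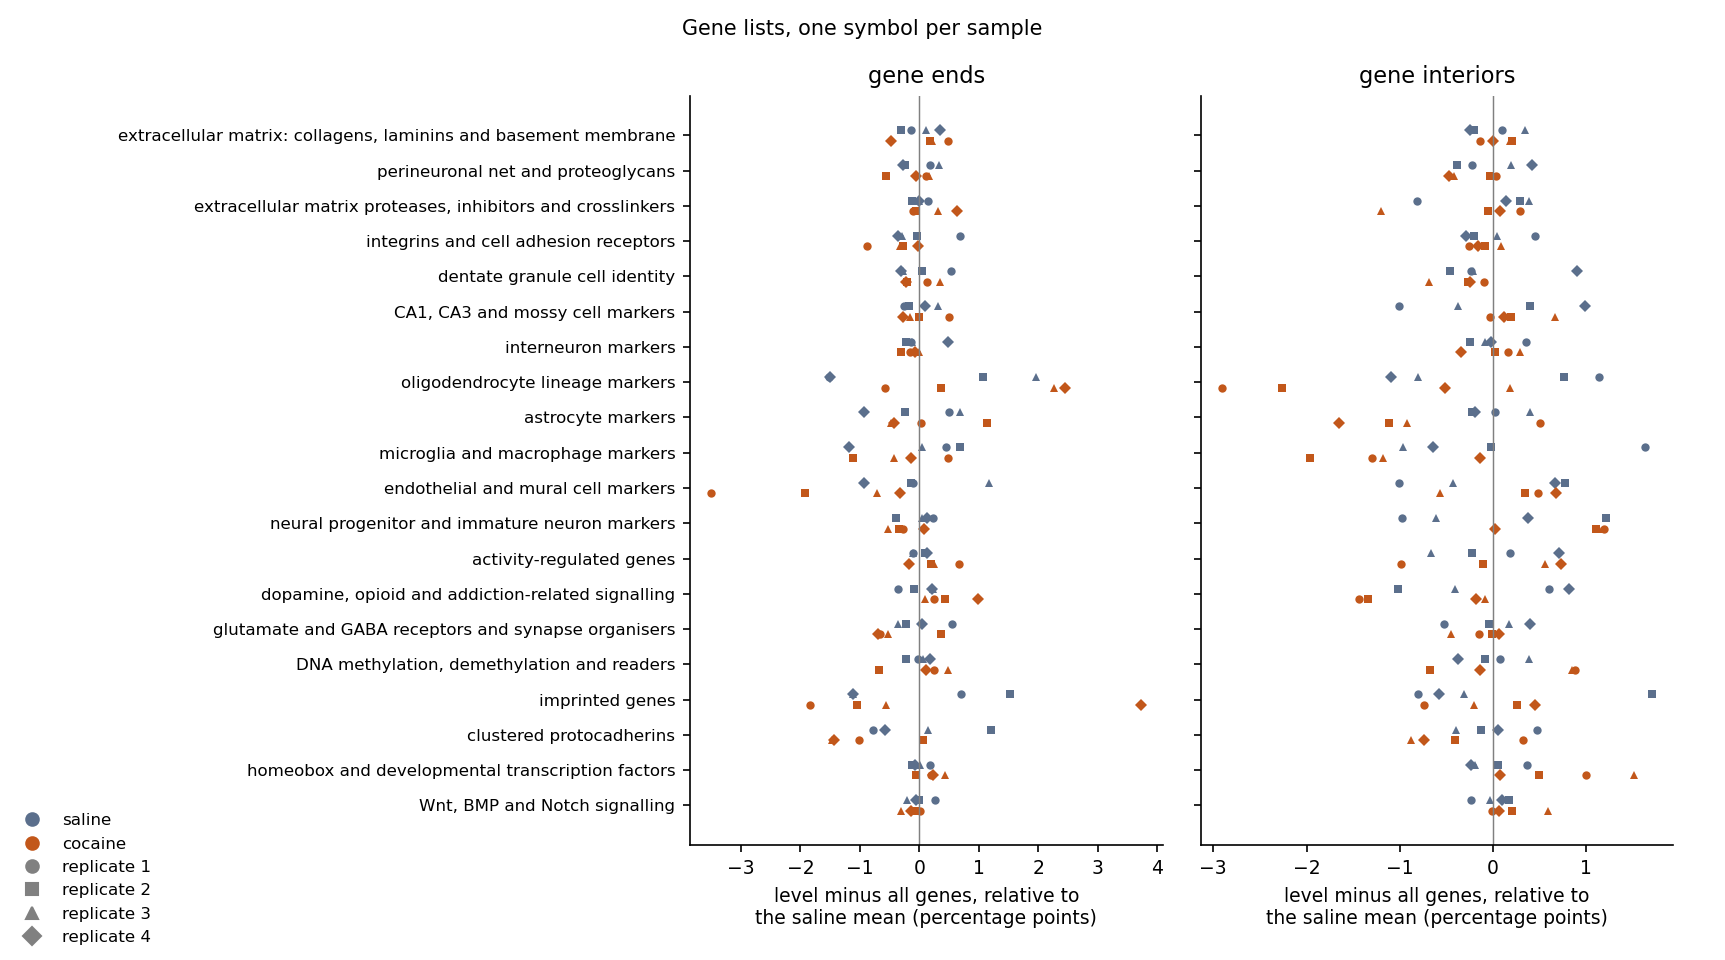
Methylation of 20 gene lists at gene ends (left) and in gene interiors (right), each as the mean over member genes minus the mean over all genes, relative to the saline mean of that list in percentage points (horizontal axes). Symbols are samples. Cocaine and saline samples overlap in each list shown, and no list passed an exact permutation p of 0.05.

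Centred on all genes, genes of DNA methylation and its readers differed by 0.0405 points at the ends of 21 genes (exact permutation p = 0.886). Their centred difference in 18 interiors was 0.230 points (exact p = 0.629). Not centred, these differences were negative, at -0.318 and -0.764 points. Within Dnmt3a, a de novo DNA methyltransferase gene, a region read 47.4% ± 9.42 in cocaine and 65.6% ± 5.48 in saline mice, and near an end of Zbtb4, a methyl-CpG binding protein gene, one read 3.31% ± 2.35 and 14.9% ± 7.85 (adjusted p = 0.876 each). Homeobox and developmental transcription factor genes had low interiors, 7.54% ± 0.397 and 7.77% ± 0.131, and their centred difference of 0.771 points over 53 genes had the smallest p of the 40 list tests (exact p = 0.0571, adjusted p = 0.727). Not centred, the difference was -0.224 points (exact p = 0.314), so the positive sign comes from the fall over all gene interiors, from 59.5% in saline to 58.5% in cocaine mice. Clustered protocadherins differed by -0.963 points at the ends of 35 genes (exact p = 0.114) and by -0.424 points in 41 interiors (exact p = 0.200), both centred. Not centred, their interiors differed by -1.42 points (exact p = 0.0286, the smallest possible). Wnt, BMP and Notch genes differed by -0.128 points at the ends of 56 genes (exact p = 0.343). Imprinted genes averaged 26.5% ± 2.80 at the ends of 37 genes in cocaine and 26.8% ± 1.35 in saline mice (exact p = 0.943 after centring). Among their best covered ends, the Zrsr1 window, on chromosome 11, read 31.5% ± 5.08 and 30.1% ± 5.25 (exact p = 0.714), and Kcnq1 read 4.37% ± 1.36 and 4.64% ± 0.858 (exact p = 0.771). The ends of Grb10 (1.24% ± 0.519 and 1.30% ± 0.694), Herc3 (0.370% ± 0.349 and 0.175% ± 0.0615) and Copg2 (0.284% ± 0.238 and 0.138% ± 0.0961) were nearly unmethylated in both groups. Of the 40 list tests, 0 had an exact p under 0.05, where 1.14 would by chance.

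Differences at neighbouring CpGs were compared to see whether they ran together along the genome. Over 1487519 pairs of CpGs within 100 bp, the cocaine minus saline differences correlated at 0.234 across pairs, and at 0.0216 for pairs over 100 and up to 500 bp apart. Pairs of CpGs are not independent replicates, and these values describe the libraries. Variance between mice was larger in cocaine than in saline mice at 52.9% of intermediate cytosines.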

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

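Of the tests in this part, strand disagreement with shared strand differences removed, mitochondrial cytosines and the splits of called regions and of merged strands were chosen only after those results had been seen, and the share of regions lower with cocaine after the leading regions had been seen, but before its values. Of 250 groups of 4 samples examined, 14 held a sample far from the other 3, and chance gives about 1 in 20, or 12.5.

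Saline 1 stands apart among the saline libraries. It lists 2236384 cytosines, next to 1890504, and at intermediate cytosines with 30 to 40 reads it has 18.7% of values at exactly 0% or 100%. Lower read depth cannot account for this 18.7%, since reads were matched and the other 7 samples reach at most 4.26%. Few original molecules behind its reads are a candidate explanation, because effective reads per cytosine, from the disagreement of both strands after removing strand differences shared by the samples, were 4.88 in saline 1 and 8.05 to 16.6 in the others. As first planned, with shared strand differences left in, the value was 2.09 against 2.27 to 3.84, but those differences dominate it in all samples, so it decides nothing, and no biological explanation was tested.

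Among regions with small p, 80.9% have the lower mean in cocaine mice. Chance cannot be excluded, since 3 of the 35 splits leaned as far to one direction, the highest other split reaching 84.1%. Saline 1 alone does not account for the lean, which was 82.7% without it, and incomplete conversion does not either, since mitochondrial cytosines differed by 0.0047 points against -2.25 at intermediate cytosines. Another mix of cell types in the dissected layer stays open. The smallest exact permutation p among marker lists of other cell types was 0.114, where 4 against 4 mice give at least 0.0286. Among alternatives, 0.0286 was reached by endothelial and mural gene ends in 2 kb windows (-1.32 points). It was also reached by astrocyte interiors not centred on all genes (-1.79 points). Protocadherin interiors not centred and homeobox gene ends weighted by reads, which mark no other cell type here, reached it as well. The astrocyte value includes the fall over all gene interiors, from 59.5% to 58.5%. Centred, it was -0.796 points (exact p = 0.143). These values thus do not show another mix. The bound written beforehand was wrong to read a missed threshold as exclusion. Cocaine self-administration itself also stays open, as the groups and these explanations were not separated further.

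Without an overdispersion term, 100675 cytosines would be called, 66462 of them lower with cocaine. Chance cannot be excluded here, since 6 of the 35 splits called as many, with 109645 in the highest other split and 90907 in the lowest. Counting reads as replicates thus may account for most of these calls. The highest split set cocaine 1, 2 and 3 with saline 1 against the rest, and it also gave 7205 regions at an unadjusted p under 0.05, against 5229 for the real one. As 7 of 35 splits matched this count, chance cannot be excluded there, although the median of the other splits was lower, at 4365.5.

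For the 1 called cytosine of the main test, chance cannot be excluded either, as it was matched by 16 of the 35 splits, with 15 in the highest other, and the 20 called with merged strands by 5 of 35, with 34 in the highest other. The same holds for the correlation of differences within 100 bp, 0.234, which was matched by 11 of 35, with 0.264 in the highest other. With 0 called regions and 0 called gene ends, all 35 splits match by construction, with 0 in the highest other, so these counts say nothing about chance.

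The remaining samples far from their group are given as values. At cytosines of high level, saline 1 had a mean of 92.5%, next to 91.8%. In the Rerg region, saline 2 read 27.5%, next to 39.6%, and at the Unc45a end it read 45.3%, next to 61.7%. At the Grb10 end, saline 1 read 2.34%, next to 1.04%, and in the Hapln3 region it read 100%, next to 92.7%. In the Mpped1 region, cocaine 3 read 3.15%, next to 11.4%, and in the Axin2 region cocaine 4 read 45.3%, next to 42.3%. Cocaine 1 read 20.4% in the Hcrtr1 region, next to 35.3%, and 28.6% in the Sox6 region, next to 36.7%. Centred on all genes, interneuron gene ends in saline 4 stood at -8.42 points, next to -9.03. Glutamate and GABA gene ends in cocaine 2 stood at -4.07 points, next to -4.96, and progenitor gene interiors in cocaine 4 at -36.4 points, next to -35.3. Mitochondrial cytosines, left out of the comparisons in the report, had a mean level of 0.105% over the 8 samples.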

How the results depend on the processing

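Alternatives chosen only after results were seen were each cytosine's own dispersion, the shares of regions lower with cocaine, the variants of neighbour correlation and spread, and leaving out saline 1 with cocaine 3. The count of called cytosines, 1, stayed at 1 with coverage minimums of 20 and 30, with 3 samples per group, without the highest coverages, without a floor on dispersion, without chromosomes X and Y and with other minimum differences. It was 20 with merged strands (4 higher and 16 lower with cocaine, where the 1 was higher), 0 with no filter on level, 0 with limma, 0 with own dispersions, 100675 with the chi-square test and 90426 with pooled Fisher's exact tests. Leaving out each sample gave 0 (without cocaine 4) to 25 (without saline 3, 3 higher and 22 lower), with 6 without saline 4. Called regions, 0, were 4631 with the chi-square test and 0 under every other alternative run on regions except the block. Called gene ends stayed at 0 under all alternatives run on them. Those did not include the chi-square test or pooled Fisher's exact tests. Apart from the removal of overdispersion, the cause of these shifts was not tested.

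The share of regions lower with cocaine, 80.9%, was 82.3% with gaps of 300 bp, 83.7% with at least 5 CpGs, 76.3% with no filter on level, 69.5% with the chi-square test, 77.0% with limma and 71.6% without saline 1 and cocaine 3. Leaving out each sample gave 69.1% (without cocaine 3) to 87.2% (without cocaine 4). For the overall difference this gave -0.460 points (without cocaine 3) to -1.01 (without cocaine 4). Over every cytosine of each sample it was -1.07 points (exact permutation p = 0.457). There saline 1 had a mean of 46.6%, against 42.3%, 42.3% and 42.5% in saline 2, 3 and 4. Cocaine mice had 41.0% to 43.8%, so this -1.07 rests on saline 1. Over common cytosines the difference was -0.797 points without saline 1. The sign was the same under all alternatives run, which did not include every cytosine without saline 1. There, saline 2, 3 and 4 lay within the range of the cocaine mice, so no fall is apparent without saline 1. The correlation of neighbours was 0.258 at a minimum of 20 reads, and the share of cytosines more variable in cocaine was 47.4% to 60.8% without single replicate numbers. The differences of the 16 named regions can move only where samples are left out, and none changed sign there. With the chi-square test 14 of them passed the threshold. List differences changed sign in 77 of 520 alternatives, and no list passed after adjustment. That says little, since the smallest possible exact permutation p is 0.0286, or 0.0571 without 1 sample, and single lists at 0.0286 (1 with 2 kb windows, 2 not centred and 1 weighted by reads) cannot pass among 40 tests.

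Methylation gave little sign that the replicate numbers pair the mice: deviations of same-numbered samples correlated at -0.0169, -0.0105, 0.00667 and 0.0772. Best matches had the same number for cocaine 4, saline 3 and saline 4 and not for the other samples. These values cannot exclude that the mice were paired in the experiment. With the number as a replicate block, called cytosines were 0 and called regions 1, near an end of Tmem267 (5.59% ± 3.72 in cocaine and 23.6% ± 17.5 in saline mice, adjusted p = 0.0119 with limma moderation, 0.876 without the block), a gene named after its values were seen. The block changed no other call, and for lists and the overall level it could not, as exact sign flips give at least p = 0.125. In simulated reads, 6% of cytosines and 88% of regions changed by 30 points were called.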

Other observations

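In this part, the counts of list members with a region at an unadjusted p under 0.05 were chosen only after no region had been called. Regions in marker genes of other cell types were taken from the 3 members of smallest p in each list, none past the threshold (adjusted p = 0.876 over all regions each). Since 80.9% of all regions with small p were lower in cocaine mice, their direction says nothing about these cell types. Pecam1, an endothelial adhesion gene, read 37.7% ± 5.70 in cocaine and 53.3% ± 4.51 in saline mice, and Sox10, a transcription factor of the oligodendrocyte lineage, read 28.2% ± 8.18 and 37.7% ± 3.00. In that lineage's list the smallest p belonged to Cspg4, given above with the proteoglycans (adjusted p = 0.0523 over the list alone). P2ry12, a microglial purinergic receptor gene, read 31.8% ± 10.4 and 44.2% ± 8.84, and Nes, an intermediate filament gene of progenitors, read 39.5% ± 8.13 and 53.9% ± 9.75. The astrocyte genes Slc1a2 and Slc4a4 went apart, with Slc1a2 at 61.0% ± 7.23 and 73.6% ± 1.33 and Slc4a4 at 46.1% ± 17.6 and 29.4% ± 12.2. Sox6, expressed in interneurons, read 34.8% ± 4.08 and 48.7% ± 7.74, and Mpped1, a marker of CA1, read 9.44% ± 4.20 and 29.3% ± 9.31.

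Developmental and imprinted genes gave values in both directions. Notch1 read 13.1% ± 7.06 in cocaine and 25.7% ± 6.47 in saline mice, Axin2 42.8% ± 1.66 and 56.3% ± 8.44, Pax9 34.1% ± 12.5 and 54.8% ± 13.97, and Gata4 34.7% ± 5.08 and 21.2% ± 8.84. A region shared by Zrsr1 and Commd1, which overlap, read 36.5% ± 7.34 and 25.5% ± 1.69, and an interior region of Grb10 read 26.7% ± 6.21 and 43.7% ± 17.9. A region shared by Pcdhgb1 and other gamma protocadherins read 19.3% ± 7.79 and 33.5% ± 12.1. Each of these had an adjusted p of 0.876.

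Oligodendrocyte lineage genes held a region at an unadjusted p under 0.05 in 6 of 15 members against 3.03 in random lists (one-sided permutation p = 0.0405, adjusted p = 0.279), and homeobox genes in 15 of 48 against 10.2 (permutation p = 0.0419, adjusted p = 0.279). Clustered protocadherins did so in 35 of 45 against 24.97 (permutation p = 0.0002, adjusted p = 0.0040), but these members share 90 distinct regions, of which 5 had a small p. Of the other lists, glutamate and GABA genes gave 22 of 43 against 18.3 (permutation p = 0.117), imprinted genes 15 of 45 against 11.1 (permutation p = 0.0950) and dentate identity genes 5 of 18 against 5.35 (permutation p = 0.694).

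Samples correlated over tested regions at 0.911 to 0.969, with a mean of 0.942 within groups and 0.942 between groups. The share of intermediate cytosines more variable in one group, 52.9%, was reached or passed in 29 of the 35 splits, with 72.3% in the highest other.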
